A study of Mus musculus and Homo sapiens with 29 samples.

How the data were processed

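The series covers chromatin immunoprecipitation and RNA sequencing of mouse E14 embryonic stem (ES) cells and of SH-SY5Y, a human neuroblastoma cell line. Of its 29 samples, 26 are chromatin immunoprecipitation or input libraries, 22 from ES cells and 4 from SH-SY5Y, and these were not analysed here. The other 3 are RNA libraries from ES cells labelled as EPOP knockout, knockout re-expressing wild-type EPOP, and knockout re-expressing EPOP with the L40A substitution, with 1 library per group. Per the labels' protocols, ES cells grew on gelatin with LIF, total RNA was extracted with Trizol, mRNA was isolated and fragmented by heat, and cDNA was made by reverse transcription. Whether RNA from several cultures was pooled into a library is not given in the sources used here.

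The RNA values came from a single table of the whole series with 22439 genes, each on 3 lines, a line per pair of libraries, giving 67317 lines. The authors' values per gene and library were read as FPKM (fragments scaled by transcript length and by the library's mapped fragments), because the columns follow the layout of gene-level test output of Cuffdiff per the file headers and Cuffdiff 2.2.1 is named per the submitters' processing notes. Those notes also name TopHat, Bowtie and deepTools, and the builds mm9, mm10 and hg19, without a role for each. The table holds the authors' p-value and q-value for each gene and pair, per the file headers, and their call of a difference, which always came with a q at or below 0.05. With 1 library per group, these values do not measure variation between replicate libraries. The lowest q, 0.0174, is shared by most called genes and does not rank them. The scaling between libraries and the gene annotation used are not given in the sources used here. The deposited column of log2 fold changes held 6160 entries that were not plain numbers and was not used. Each library occurs in 2 pairs, and the values in its 2 copies differed for 1 gene per library, for which the mean was taken.

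The table prints Ensembl gene identifiers with symbols and positions. Of its genes, 20705 matched a gene of the RefSeq annotation of GRCm38.p6 by symbol, and 99.9% of these overlapped it on the same chromosome, so positions are given on GRCm38 (mm10). Starts in the table count from 0, because 6947 genes had the RefSeq start after adding 1 and 543 as printed, and 1 was added to every start. In the table, 3583 genes share a position entry with another gene, and their values cannot be separated by position.

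FPKM tables hold no read counts, so absolute depth is unknown and no counting interval was computed. Relative depth was estimated from genes with values above 0 and under 0.2 FPKM in both libraries of a pair, where a gene covered by the same small number of fragments gives a fixed ratio of values. The most populated window of log2 ratios, 0.04 wide, was taken, and the value per fragment includes any scaling by the authors. A value of exactly 0 can be a failed estimate in this table, so genes at 0 are described as listed at 0.

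Libraries were compared as log2((a + 1)/(b + 1)) of the FPKM values, which understates the change of low genes. The 12165 genes at 1 FPKM or more in at least 1 library were used. With 1 library per group there is no replicate error, so no p-value across genes was computed, and genes at least 2-fold apart (an absolute log2 value of 1 or more) were counted by size. For genes 2-fold apart between a pair, the position of the third library between the pair was computed on the log2 scale as 0 at the first and 1 at the second. Libraries that differ by equal noise alone give a median of 0.5, and the 95% interval of each median was taken across genes, which are not replicates.

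For 25 gene lists fixed before the data were examined, the median log2 fold was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list was taken to stand apart when its median lay outside the central 95% of the random medians. This describes these libraries and is not a test of the conditions. Because the knockout library enters both comparisons with it, 100 sets of unchanged libraries with equal noise were simulated against a shared library, with noise drawn from the difference of the rescue libraries in 20 expression bins.

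Named genes followed a rule fixed before the data were examined. It took Epop (E130012A19Rik in the table), Actb and Gapdh; the 12 genes with the largest log2 fold in each direction at a mean of 2 FPKM or more, leaving out uncharacterised symbols, small RNAs, joined and duplicated symbols; and in each list up to 4 members with the largest absolute log2 fold. Genes outside the rule are marked as chosen after their values were seen. Some genes are not reported here.

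The alternatives fixed before the data were examined were a pseudocount of 0.1, no filter beyond a value above 0, a filter of 5 FPKM, rescaling to a common median ratio or upper quartile, a 1.5-fold threshold, random lists without matching, and the authors' own calls. Leaving out genes listed at 0 in any library, and a mean of 20 FPKM or more, were chosen after seeing the data. The steps were tested on simulated data built from the real expression levels with 200 changed genes. The changed genes lay at about 5 FPKM or more, and folds were added on the log2(FPKM + 1) scale. For the wild-type rescue against the knockout, 98.0% of 3-fold and 8.00% of 1.5-fold changes were counted as 2-fold apart. Recovery of changes in lower genes was not simulated, although 12165 genes were in the simulation. Of 11965 unchanged genes 3.41% were counted, a share set by the noise, which was drawn from the difference of the rescue libraries. Of 100 simulated lists of 20 unchanged genes, 5 lay outside the central range, and of 100 lists raised by 0.3 on the log2 scale, 96 lay above it. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.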

Results

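The RNA libraries addressed which transcripts differ when EPOP, a protein that binds Elongin BC and the Polycomb repressive complex PRC2 in mouse ES cells, is put back into knockout cells, and whether the L40A substitution in EPOP, which lies in its Elongin BC binding region, alters the result. There were 3 libraries, 1 each of the knockout, the wild-type rescue and the L40A rescue. No replicate error could be computed, and every difference below is between single libraries. FPKM values summed to 488548 in the knockout, 463008 in the wild-type rescue and 409792 in the L40A rescue, and 11305, 11365 and 11463 genes reached 1 FPKM. A fragment was worth 1.12 times as much in the wild-type rescue and 1.18 times as much in the L40A rescue as in the knockout, which corresponds to relative depths of 0.890 and 0.847.

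Transcripts of the targeted gene, Epop (E130012A19Rik, chromosome 11, 97627389 to 97629702), were present in all libraries, at 62.2 FPKM in the knockout, 76.7 in the wild-type rescue and 99.3 in the L40A rescue. The knockout library was the lowest, with the wild-type rescue 1.23-fold and the L40A rescue 1.60-fold higher. The authors' deposited table called neither difference, with q of 0.688 and 0.142. The labels do not say which part of the gene was disrupted, so the transcript level does not check the knockout, and RNA of cells with intact Epop was not analysed here. Actb, a cytoskeletal actin used as a control, was close to level at 707, 730 and 719 FPKM. Gapdh, a glycolytic enzyme that is abundant in most cells, was listed at only 3.54, 2.85 and 5.43 FPKM.

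**Figure D1:**
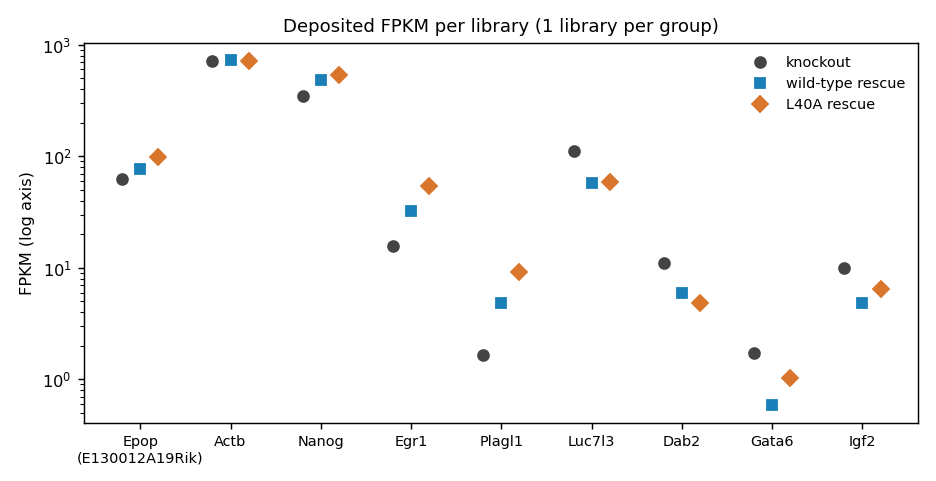
FPKM on a log axis for selected genes in the knockout (circles), wild-type rescue (squares) and L40A rescue (diamonds), with 1 library per group and no error bars. Epop transcripts were present in all libraries (62.2 to 99.3 FPKM); the genes shown were in part chosen after their values were seen.

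The wild-type rescue against the knockout asked what the wild-type protein changes. Among 12165 genes, 209 were at least 2-fold higher and 207 at least 2-fold lower in the wild-type rescue. The split was 50.2% higher, 48.7% after median-ratio scaling and 42.5% after upper-quartile scaling (188 higher and 254 lower). The group that stood lowest was the primitive and parietal endoderm list, genes of the extraembryonic lineage that ES cell cultures form spontaneously. Its 16 members had a median log2 fold of -0.35, at percentile 0.040 of matched random lists. The endocytic adaptor Dab2 was listed at 11.0 FPKM in the knockout and 5.99 in the wild-type rescue, the transcription factor Gata6 at 1.71 and 0.584, and Sox17, an endoderm transcription factor, at 1.57 and 0.543. No member reached the 2-fold size with the pseudocount of 1, although the plain ratio of knockout to wild-type rescue was 2.93 for Gata6 and 2.90 for Sox17.

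Core pluripotency genes were near level in this comparison. The list of naive and general pluripotency genes had a median log2 fold of 0.06 over 24 members, at percentile 44.6, and no member was 2-fold apart. Nanog, a transcription factor of the naive state, was the furthest apart, at 345 FPKM in the knockout and 481 in the wild-type rescue. The subunits of PRC2 had a median of 0.00 over 12 members, with Ezh2, its methyltransferase, at 63.9 and 73.4 FPKM. The list of Elongin BC, its cullin partners and Usp7 had a median of 0.16 over 10 members, at percentile 90.8, with Usp7, a deubiquitinase, at 60.9 and 72.3 FPKM.

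Several lists stood higher in the wild-type rescue, among them the replication-dependent histone genes set up as a sign of RNA quality (median 0.20, percentile 99.9, 9 members 2-fold higher and 1 lower). The other lists come from the same library. Imprinted genes had a median of 0.21 over 23 members (percentile 99.4), led by Plagl1, a zinc finger transcription factor, at 1.64 and 4.79 FPKM, while Igf2, a growth factor, went the other way at 9.95 and 4.81. Targets of p53 had a median of 0.21 over 23 members (percentile 99.8), with 15 above 0, 8 below and none 2-fold apart. Germline genes had a median of 0.31 over 21 members (percentile 99.9), with 2 members 2-fold higher and 2 lower. Tex101, a germ cell surface protein, was listed at 0.333 and 2.39 FPKM and Mael, a piRNA pathway protein, at 6.25 and 13.6, whereas Sycp1, of the synaptonemal complex, was at 2.46 and 0.694. The germline list lay inside the central range at percentile 71.7 without the filter on low values (median 0.05) and at 88.7 with the filter of 5 FPKM (median 0.15). Of 39 Hox genes 8 passed the filter, with a median of 0.41 (percentile 98.2), and Hoxc4 was the only member 2-fold higher, at 2.43 and 7.46 FPKM. The Hox median was 0.90 with the pseudocount of 0.1 and 0.17 over 38 members without the filter, and the percentile was 97.45, just inside the range, when genes listed at 0 were left out. Upper-quartile scaling brought the medians of imprinted genes and p53 targets to 0.10 and 0.11, at percentiles 99.45 and 99.85.

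The largest size differences at a mean of 2 FPKM or more were mostly in genes with low values, and many involved a value of 0. B3gnt2, a glycosyltransferase, was listed at 0.236 FPKM in the knockout and 7.27 in the wild-type rescue, and Immp2l, a mitochondrial inner membrane peptidase, at 1.52 and 17.6. Smim4, a small membrane protein, was listed at 16.0 and 1.33, Gtf2a2, a subunit of the general factor TFIIA, at 20.5 and 4.85, and Etf1, the translation termination factor, at 204 and 57.4. The light chain segments Igkv12-89 and Iglv3 were listed at 7.93 and 6.31 FPKM in the knockout and at 0 in the wild-type rescue. Of these genes the authors' deposited table called only Gtf2a2, with q of 0.624 for B3gnt2, 0.121 for Immp2l, 0.750 for Smim4 and 0.661 for Etf1. Of the 416 genes 2-fold apart, 161 were listed at 0 in a library, and 337 had a mean under 5 FPKM, 7.39% of that class, against 0.520% of genes at 20 or more. The plot of shares by expression gives all classes.

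The authors' deposited table called 48 genes in this pair, 24 higher and 24 lower in the wild-type rescue, and 40 of them were listed at 0 in a library. Among the other 8, some of them chosen after their values were seen, were Egr1 and Plagl1, higher, and Luc7l3, Igf2, Htra2, Stx6 and Gtf2a2, lower. Luc7l3, a splicing factor, was the most abundant, at 112 FPKM in the knockout and 57.8 in the wild-type rescue (q = 0.0174 in the authors' deposited table). Egr1, an immediate early transcription factor, was at 15.7 and 32.2.

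**Figure D2:**
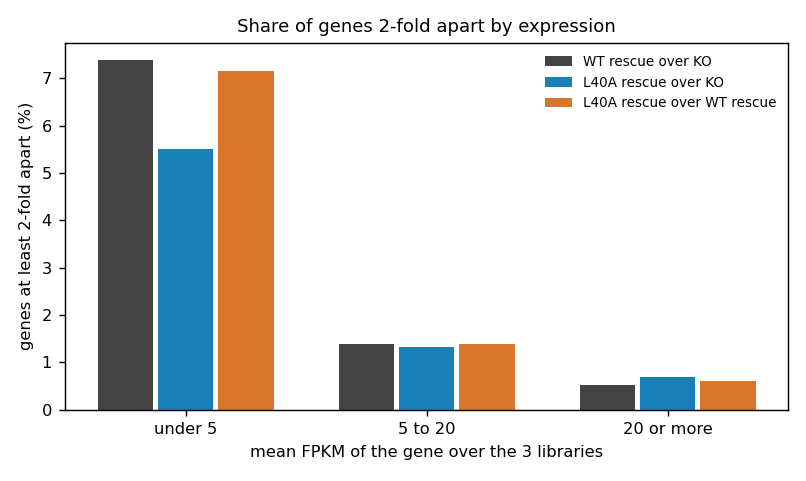
Share of genes at least 2-fold apart (percent, vertical axis) in each pair of libraries, by mean FPKM over the 3 libraries (horizontal axis), with 1 library per group and no error bars. The share was 7.39%, 5.50% and 7.17% under 5 FPKM and 0.520%, 0.682% and 0.617% at 20 or more.

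The L40A rescue against the knockout asked what the substituted protein changes. In the L40A rescue 181 genes were at least 2-fold higher and 151 at least 2-fold lower than in the knockout. Replication-dependent histone genes stood furthest from matched lists, with a median log2 fold of 0.67 over 55 members, above all matched lists at percentile 100, and 17 members 2-fold higher against 1 lower. This list was set up as a sign of RNA quality, because mRNAs of these genes lack a poly(A) tail and their reading depends on how RNA was selected. Hist1h3g was listed at 1.75 FPKM in the knockout and 7.41 in the L40A rescue, and Hist1h2bh at 1.29 and 5.72; histone genes have near-identical copies, so single members are uncertain. Against the same knockout library the primitive and parietal endoderm list, like the imprinted and p53 lists below, is no independent repeat of the wild-type result. It had a median of -0.16 over 16 members at percentile 0.720, with 12 members below 0 and 4 above. Dab2, at 11.0 and 4.87 FPKM, was its only member 2-fold lower.

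In the same library, where the RNA quality list stood this high, imprinted genes had a median of 0.31 (percentile 99.8), with Plagl1 at 1.64 and 9.12 FPKM and Mest at 11.7 and 21.8. Targets of p53 had a median of 0.27 (percentile 99.2), with 21 of 23 members above 0 but none 2-fold apart. Germline genes had a median of 0.27 (percentile 98.7), which became percentile 84.3 without the filter on low values (median 0.15) and 33.05 with the filter of 5 FPKM (median 0.05). Hox genes had a median of 0.38 (percentile 96.97, inside the range) with 7 of 8 above 0, close to the wild-type rescue. Without matching they lay outside the range at percentile 98.75. Cytosolic ribosomal protein genes had a median of -0.02 over 77 members, below all matched lists, whose central median was 0.13; their mean was 0.00. Immediate early genes as a list lay inside the range, at percentile 73.3, and held 2 members 2-fold higher, Egr1 at 15.7 and 53.6 FPKM and Ctgf, a matricellular protein, at 3.89 and 9.11; Ctgf was under 2-fold after either rescaling. Pluripotency genes had a median of 0.20 (percentile 86.8), PRC2 subunits 0.23 (percentile 89.9) and the Elongin BC list 0.17 (percentile 70.8), and no member of these lists was 2-fold apart. Upper-quartile scaling brought the medians of imprinted genes, p53 targets and germline genes to 0.17, 0.13 and 0.16 and that of the endoderm list to -0.28, with percentiles of 99.85, 99.1, 98.9 and 0.450.

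Among the genes furthest apart, Il6st, the shared receptor subunit of the LIF pathway, was listed at 40.6 FPKM in the knockout and 168 in the L40A rescue, Pnrc2, an mRNA decay adaptor, at 35.2 and 213, and Polr2k, an RNA polymerase subunit, at 1.73 and 11.0. Smim4 was again low, at 16.0 and 1.24, and Plac8 was at 7.36 and 1.86. The authors' deposited table called none of these, with q of 0.599 for Il6st, 0.168 for Pnrc2, 0.442 for Polr2k and 0.741 for Smim4. The 6 mitochondrially encoded transcripts above 1000 FPKM in each library were lower, with mt-Nd4 at 14007 and 4893 FPKM, mt-Cytb at 26805 and 10089, and mt-Nd1 at 35403 and 13479. Of those with low values, mt-Nd4l was higher, at 0 and 11.6, and mt-Nd3 was near level, at 4.52 and 4.79. The low mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8 were lower. The mitochondrial share of all FPKM was 43.1% in the knockout, 37.4% in the wild-type rescue and 26.3% in the L40A rescue, or 43.1%, 33.7% and 23.7% without mt-Co1. This gene was listed at 0 in the knockout and at 26197 and 14065 in the rescues, and the authors' deposited table marks it as not tested for an excess of data.

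The authors' deposited table called 35 genes in this pair, 20 higher and 15 lower in the L40A rescue, with 13 listed at 0 in a library. Of the 22 above 0 in both libraries, 15 were higher. The genes named next were chosen after their values were seen. They included Usp9x, a deubiquitinase, at 57.7 and 101 FPKM, Jam2, an adhesion molecule, at 79.6 and 142, and Qk, an RNA-binding protein, at 36.5 and 61.6. Luc7l3 was lower, at 112 and 58.5. The median of all genes was 0.10 in this pair. It became 0.00 after median-ratio scaling and -0.02 after upper-quartile scaling, and as rescaling shifts all genes with the median, the split of 2-fold genes went from 54.5% higher to 45.0% (144 higher and 176 lower) and 43.4% (145 higher and 189 lower).

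The direct comparison of the rescues asked what the substitution changes relative to the wild-type protein. In the L40A rescue 236 genes were at least 2-fold higher and 173 at least 2-fold lower than in the wild-type rescue, 57.7% higher, or 51.5% after median-ratio scaling. Histone genes, the sign of RNA quality, again stood highest, with a median log2 fold of 0.37 over 55 members (percentile 100), 16 of them 2-fold higher and 7 lower, and with the filter of 5 FPKM the median was 0.61 over 25 members. The primitive and parietal endoderm list did not stand apart, with a median of 0.04 at percentile 33.3, nor did imprinted genes at 0.10 (percentile 58.7) or p53 targets at 0.10 (percentile 51.2). PRC2 subunits had a median of 0.17 (percentile 89.5), with all 12 above 0, and the Elongin BC list 0.06 (percentile 32.6). Hox genes had a median of -0.29 (percentile 2.90), inside the range, but lay outside it at percentile 0.22 without matching.

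Germline genes had a median of -0.10 (percentile 2.08), although their mean was 0.08, and Hormad1, a meiotic chromosome axis protein, was listed at 1.17 FPKM in the wild-type rescue and 4.09 in the L40A rescue. This list lay inside the range at percentile 2.80 with the pseudocount of 0.1 (median -0.10), 2.70 with the filter of 5 FPKM (median -0.10) and 21.9 without the filter on low values (median 0.00). Ribosomal protein genes had a median of -0.01 (percentile 0.130) and a mean of 0.01. Y-linked genes, with 3 members, had a median of -0.41 (percentile 2.02), inside the range at percentile 2.70 after median-ratio scaling (median -0.48) and at 2.95 with the pseudocount of 0.1 (median -0.44). Etf1 was listed at 57.4 FPKM in the wild-type rescue and 581 in the L40A rescue, and Il6st at 45.8 and 168. Ccl27a, a chemokine, was at 13.1 and 1.64, and Masp2, a complement protease, at 7.40 and 1.04. Thymosin genes Tmsb15b1 and Tmsb15l were lower in the L40A rescue, at 16.7 and 3.60 FPKM and at 15.0 and 0, and as near-identical copies they are uncertain. The authors' deposited table called none of the genes named here from Etf1 to Tmsb15l between the rescues.

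The authors' deposited table called 52 genes between the rescues, 32 higher and 20 lower in the L40A rescue, and 44 were listed at 0 in a library. Of the other 8, chosen after their values were seen, Stx6, a syntaxin of endosomal transport, was at 4.14 and 10.7 FPKM and Bcl7b, a chromatin remodeller subunit, at 9.85 and 23.4. Across the pairs, that table called 108 genes at least once. It called 5 in both rescues against the knockout, namely Crh, Egr1, Hist1h2ab, Luc7l3 and Plagl1, and none in all 3 pairs.

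**Figure D3:**
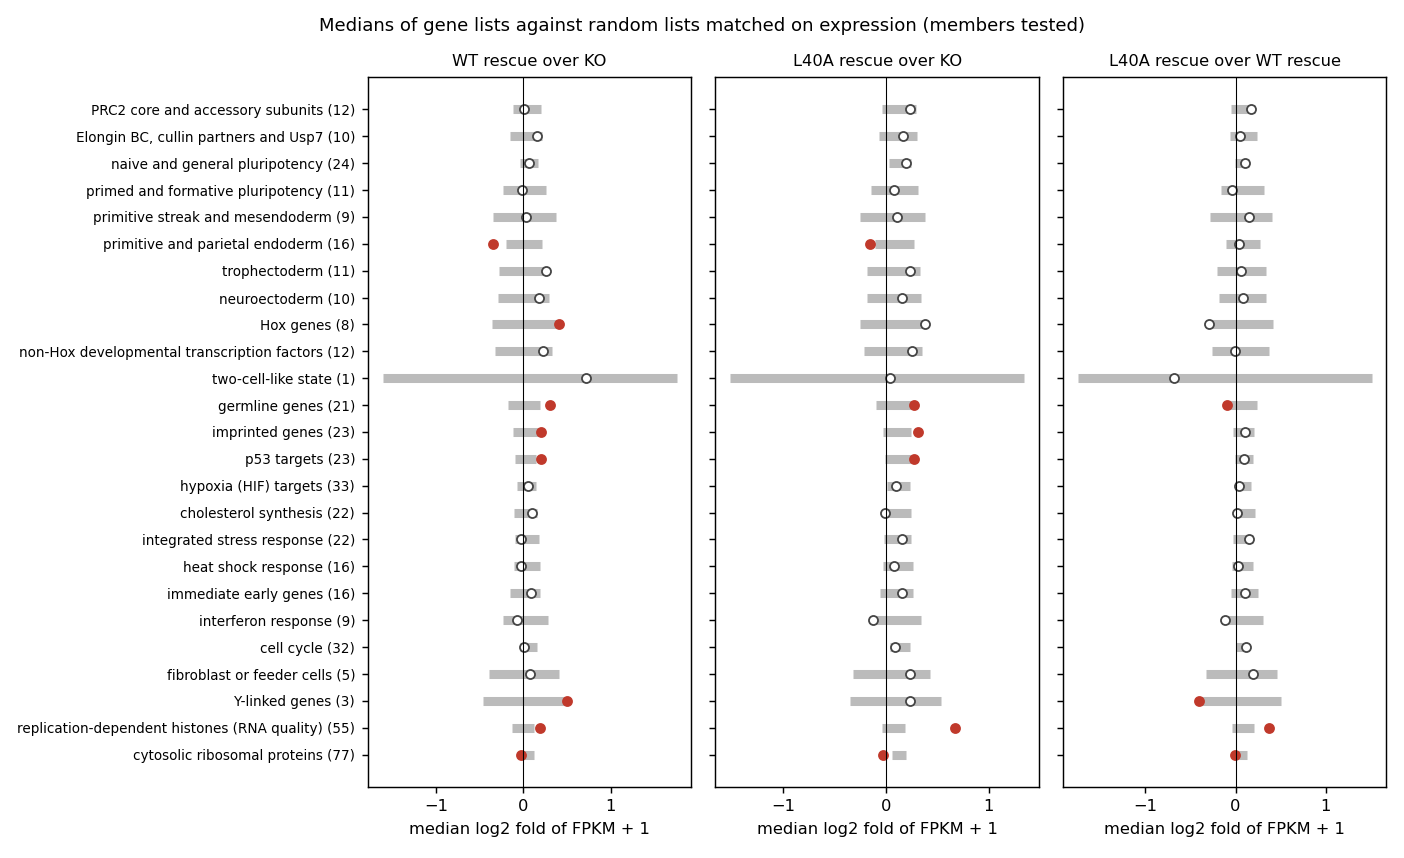
Median log2 fold of each gene list (points, horizontal axis, log2 of FPKM + 1) in the 3 pairs of libraries, with the central 95% of medians of matched random lists (grey bars) and the number of members tested in brackets. Filled points lie outside the bars, as for primitive and parietal endoderm in the wild-type rescue over the knockout (-0.35).

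The third library's position was used to ask whether the L40A rescue lies nearer the knockout or the wild-type rescue. Over the 416 genes 2-fold apart between knockout and wild-type rescue, the L40A rescue lay at a median position of 0.364 (interval 0.289 to 0.440), where 0 is the knockout and 1 the wild-type rescue. For the 209 genes higher in the wild-type rescue the position was 0.264 and for the 207 lower genes 0.491. At a mean of 20 FPKM or more only 16 genes remained, with a position of 0.173 (interval -0.151 to 0.939). By the same measure the knockout lay at 0.638 between the wild-type and L40A rescues, and the wild-type rescue at 0.602 between the knockout and the L40A rescue. More noise in a single library also moves these values from 0.5.

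Both rescues were compared with the same knockout library. The log2 folds of the rescues had r = 0.55 across genes, which are not independent replicates, against 0.50 in simulated unchanged libraries, and a covariance of 0.112 against 0.0915. Most of this covariance excess of 0.0201 comes from mt-Co1, listed at 0 in the knockout, with log2 folds of 14.7 and 13.8. The simulated noise was drawn without mitochondrial genes, so these values show no shared change across many genes. There were 46 genes 2-fold higher in both rescues, against 67.0 in the simulation and 3.11 for independent lists, and 79 lower in both, against 64.4 and 2.57. Genes such as B3gnt2, Plagl1, Smim4 and Ppih were among them. At 20 FPKM or more, without mitochondrial genes, the covariance was 0.0813 against 0.0295, a difference of 0.0519. The counts there showed no excess, with 1 gene higher in both against 3.66 simulated and 3 lower in both against 4.57. In this class Gm10198 and Gm17374, at 342 and 111 FPKM in the knockout, were listed at 0 in both rescues. Their log2 folds were -8.42 and -6.81 in each rescue. Folds of this size weigh heavily on a covariance, and most of its excess in this class comes from Gm10198 and Gm17374. The covariance was not computed without them. With a single knockout library the controls could not be split, and part of the excess may come from that library.

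The remaining lists lay inside the central 95% of matched random lists in all pairs. These were primed pluripotency, primitive streak, trophectoderm, neuroectoderm, other developmental transcription factors, hypoxia, cholesterol synthesis, the integrated stress response, heat shock, interferon response, cell cycle and fibroblast or feeder genes, the last with 5 members. Trophectoderm lay outside it without matching, at percentile 98.37 in the wild-type rescue over the knockout. The list of the 2-cell-like state had 1 of 18 members tested, so its position says nothing about that state. In the wild-type rescue over the knockout, the 3 Y-linked genes had a median of 0.50 (percentile 97.7), histone genes 0.20 (percentile 99.9) and ribosomal protein genes -0.03 (percentile 0.960). In that pair the histone list had a median of 0.39 when genes listed at 0 were left out, and it lay inside the range at percentile 95.05 with the filter of 5 FPKM (median 0.12), and the ribosomal list at 15.5 without matching. At a mean of 20 FPKM or more, where 8 imprinted genes and 13 p53 targets were left, imprinted genes lay inside it at percentiles 95.35 and 95.15 for the wild-type and L40A rescues over the knockout, and p53 targets at 95 for the L40A rescue, while the medians stayed close, at 0.20, 0.30 and 0.27. Over all lists and pairs 18 of 75 medians lay outside the range, where 3.75 would for lists of randomly drawn genes. The pairs share libraries and members of a list may vary together, so this excess is not a test against chance.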

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

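The test of scaling and the test of the knockout library's reading were chosen only after the result was seen, and the knockout-library test was added once the gene length result was known. The effects of the rescues against the knockout went in opposite directions, each by 2-fold or more, for 7 of the 12165 genes tested, against a mean of 2.91 and at most 7 in 100 simulated sets of unchanged libraries sharing a knockout. With 1 library per group the difference was not tested against replicates. The 4 of these with characterised symbols and a mean of 2 FPKM or more are given here. Etf1 had log2 folds of -1.81 in the wild-type rescue and 1.505 in the L40A rescue, at 204 FPKM in the knockout. Ly96 had -1.44 and 1.09, Sct -1.31 and 1.44, and Cnfn 1.03 and -1.44, and each of these was listed at 0 in a rescue library. Between the rescues the authors' deposited table gave q of 0.563 for Etf1, 0.116 for Ly96, 0.0515 for Cnfn and 0.0174 for Sct, and of these 4 it called only Sct.

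Gapdh and the mitochondrial genes from mt-Co2 to mt-Nd4l were listed at 11.6 FPKM or less in each library, although the neighbouring mt-Nd4 was at 14007 FPKM in the knockout. A candidate explanation is that reads aligning to several places were left out. Across 80 cytosolic ribosomal protein genes, the number of annotated copies with a -ps symbol and the mean FPKM had Spearman rho = -0.327 (two-sided permutation test across genes, p = 0.00321, n = 80), which goes with it. Copies under other symbols were not counted. The median was 137 FPKM for the 17 genes without a -ps copy and 20.2 for the 34 genes with 3 or more. Of the 17, 4 were under 10 FPKM too, against 12 of the 34. The -ps count does not account for these 4, and whether they have copies under other symbols was not examined. No biological explanation was tested, and the authors' handling of such reads is not given in the sources used here.

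Mitochondrial transcripts were higher in the knockout than in the L40A rescue, with a median log2 fold of 1.37 over the 6 genes above 1000 FPKM, all 6 ordered knockout, wild-type rescue, L40A rescue. Of these the authors' deposited table called only mt-Nd4 in this pair (q = 0.0174), with q from 0.0692 for mt-Nd2 to 0.734 for mt-Nd6 in the others. Among the 6, mt-Nd5 and mt-Nd6 share a position entry, so their values cannot be separated by position. Carry-over of RNA without a poly(A) tail in the knockout would raise histone mRNAs, but these were lower there, at -0.59 relative to matched genes. This bears only on RNA without a tail. A difference between libraries in the selection of RNA with a tail was not tested. Scaling between libraries would move all other genes, whose median was -0.10. A difference due to EPOP status stays open and untested, as does RNA handling in a single library.

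Among genes that the authors' deposited table called higher in the L40A rescue than in the knockout, the 15 above 0 in both libraries had a median span of 69.9 kb (13 with a span) against 22.4 kb for all genes tested, while the other 5, listed at 0 in the knockout, were shorter, at 10.3 kb (3 with a span). A length trend was present (Spearman rho 0.176 across genes), and genes matched to the 13 on expression and span had a median log2 fold of 0.20 against 0.10 for all genes with a span. Span had rho of 0.0770 for the wild-type rescue over the knockout and 0.0970 for the L40A over the wild-type rescue. The trend was thus not confined to pairs with the knockout. The called genes lay 0.75 above their matches (0.95 against 0.20), but they had been selected by that same fold, so a gap of this kind, set beforehand as evidence against length, was wrong as a bound and excludes nothing. A low reading in the knockout library alone may contribute: over the 15 called genes the wild-type rescue lay at a median position of 0.661 between the knockout and the L40A rescue (interval 0.545 to 0.756), nearer the L40A rescue. An effect of EPOP shared by both proteins predicts that too, so length, the knockout library and EPOP status all stay open.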

How the results depend on the processing

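Absolute depth is unknown for FPKM values, and differences between single libraries have no replicate check. No paired analysis was possible because each RNA group has 1 library and the numbered chromatin libraries were not analysed here. Leaving out genes listed at 0 and the mean of 20 FPKM or more were chosen after seeing the data. Counts are given as higher and lower for the wild-type rescue against the knockout, the L40A rescue against the knockout, and the L40A against the wild-type rescue. A pseudocount of 0.1 gave 503 and 479, 474 and 339, and 562 and 422. The filter of 5 FPKM gave 61 and 64, 69 and 47, and 77 and 49, since fewer genes were tested. The 1.5-fold threshold gave 724 and 712, 842 and 457, and 854 and 541. Leaving out genes listed at 0 gave 128 and 112, 118 and 77, and 143 and 94. A mean of 20 FPKM or more gave 6 and 10, 8 and 13, and 11 and 8, and moved the L40A position to 0.173; the cause was not tested. The authors' own calls gave 24 and 24, 20 and 15, and 32 and 20. Both rescalings and the absence of a filter left the counts within 1.5 times and the position inside its interval. Rescaling did move medians of lists by over 1.5 times, since it shifts all genes: in the L40A rescue against the knockout, median-ratio and upper-quartile scaling gave 0.20 and 0.17 for imprinted genes and 0.16 and 0.13 for p53 targets. Other choices moved medians as far: the Hox list in the wild-type rescue had 0.90 with the pseudocount of 0.1 and 0.17 without a filter, and the germline list there had 0.05 without a filter. The germline list in the L40A rescue against the knockout turned to percentile 33.05 with the filter of 5 FPKM, which leaves fewer members. Of other percentiles of lists, 14 moved inside the central 95%, 3 moved outside it and 169 kept their side. Of the named genes' log2 folds, 54 crossed the 2-fold size and 2041 did not.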

Other observations

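The test of low expression was chosen only after the result was seen. Some predicted genes differed in the L40A rescue, in both directions. Those named were chosen after their values were seen, and predicted genes were not examined as a list. In the authors' deposited table Gm10800 was at 4652 FPKM in the knockout, 4412 in the wild-type rescue and 1696 in the L40A rescue, Gm10801 at 947, 1300 and 373, and Gm10717 at 123, 81.1 and 46.5, while Gm11808 was at 116, 79.0 and 188, called higher in the L40A than in the wild-type rescue. Of genes that table called higher in the L40A rescue than in the knockout, also chosen after their values were seen, Ptbp3, a splicing regulator, was at 21.8, 46.1 and 49.0 FPKM, Cnot4, of the deadenylase complex, at 19.8, 32.5 and 37.7, and Dmrt1, a germ cell transcription factor, at 28.4, 42.8 and 56.2.

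Noise of genes with low expression may account for most of the genes 2-fold apart. The share 2-fold apart at 1 to 5 FPKM was at least 5.39 times the share at 20 or more in each pair, 5.23% against 0.520% for the wild-type rescue and the knockout. The same excess would follow from real differences in genes with low expression, which these libraries cannot separate from noise.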
